A study of Mus musculus with 50 samples.

How the data were processed

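RNA from 31 lung tumours and 19 normal lungs of mice was measured on Affymetrix oligonucleotide arrays, 1 array per sample. Per the labels' protocols, the tumours arose in mice with a latent Kras allele, the mice were 5 to 6 months old, and individual tumours of 3 to 8 mm were dissected from lungs kept in RNAlater. RNA was extracted with Trizol, purified on a column and checked by gel electrophoresis, and the biotin-labelled cRNA was stained with streptavidin-phycoerythrin and antibody amplification, per the labels' protocols. The authors deposited 1 intensity per probe set and array on a linear scale. The summary method, the background correction and the scaling behind these intensities are not given in the sources used here. The deposited columns were already close to a common scale: the median intensity of an array ranged from 217.7 to 233.9.

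The table held 12422 probe sets and no control probe sets. The platform annotation, which can be old, named 1 gene for 10833 probe sets, several for 396 and none for 1193; only probe sets with 1 gene were used by name. Their gene identifiers matched the RefSeq table of assembly GRCm38.p6 for 10817 probe sets, and 0 symbols changed. No genomic coordinates are given because no build is named for the array. No probe set was named Kras, so the gene itself was not analysed here.

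Each array was scaled so that its 75th percentile equalled the median of that percentile over arrays, 484.6, with factors from 0.952 to 1.064. Values under 20 were set to 20 and log2 was taken. A gene was represented by the probe set with the highest mean over all arrays, which gave 8251 genes, of which 2073 had several probe sets. Where a named gene's other probe sets passed in the opposite direction, or did not pass at a large difference, the text says so. No dim probe sets were removed. For arrays, the number of samples limits the precision, and signal close to the floor compresses differences.

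The table held 4360 values listed at exactly 0, which is 0.702% of all values, on 7 to 558 probe sets per array. Of these, 71.5% lay at probe sets whose median on the other arrays was above 100, which says little because the median over all probe sets was 226. Some genes had a second probe set that followed the first across arrays (r of at least 0.6), which gave 355 pairs of a zero and a second probe set, from 147 genes. A zero can enter more than 1 pair. The second probe set lay in the highest 25% of its own values at 68.5% of these pairs, and in the lowest 25% at 9.30%. At 124 genes that differed at least 2-fold among measured values, 97.0% of 298 zeros fell in the group with the higher measured values, against 43.6% from the group sizes alone. The design set before the data were examined puts such values at the floor, and the counts and tests below follow it. For a gene with zeros, the text says that it was listed at 0 and gives measured deposited intensities, with no mean or fold. Log2 differences of such genes come from the fit with zeros taken as missing, except for 1 within a number range among the alternatives. Differences at a gene's other probe sets have zeros at the floor. That fit was added after the data were seen. In its list tests, missing values were filled with the group mean of that probe set. Its values are given where the call of a list changed or a count of its members moved by over 1.5 times, and beside some other results.

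Tumours were compared with normal lungs with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with no covariates and Benjamini-Hochberg adjustment over the 8251 genes; genes were called at an adjusted p under 0.05. Differences are log2 tumour minus normal with their SE, and levels are mean log2 intensity ± SD over 31 tumours and 19 normal lungs. In 1 simulated data set made from these arrays, with 200 of 8251 genes changed, the fit called 60% of the genes changed by 0.25 on the log2 scale. It called 86% of those changed by 0.5 and 100% of those changed by 1 or 2, and 0% of its calls were false. This single draw, with far fewer changed genes than were called below, does not set the false rate. Of 99 random regroupings of the arrays, 5 called at least 1 gene. The labels do not tie tumours to mice. P-values therefore measure the spread between samples and are too small if tumours share a mouse.

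Before the data were examined, 30 gene lists were fixed. They held 579 genes, of which 470 were measured. Lists with at least 5 measured members were tested with camera (preset correlation 0.01), adjusted over 29 lists, and again with the correlation estimated from the data. For each tested list the text also gives how many members passed over all genes tested and adjusted over the list alone. Named genes followed a fixed rule: the 12 largest rises and the 12 largest falls among called genes; in each list the 2 members with the smallest adjusted p in the majority direction and 1 in the other direction; members of the sample handling lists as values; and genes whose probe sets passed in opposite directions. Other names were chosen after their values were seen.

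A list score was the mean over members of the log2 value minus the gene's mean over the samples compared. For 8 pairs of lists, scores were correlated across tumours, and separately across normal lungs. Pearson's r and Spearman's rho were tested by a two-sided permutation test with 100000 resamples, adjusted over the 8 pairs. The SD of each gene was compared between groups by 10000 permutations of group-centred values. Alternatives covered quantile normalization, median centring, the values as deposited, floors of 10 and 100, filters on dim genes, the mean of probe sets, every probe set on its own, other variance models, a rank test, array weights, a residual component, ranges of tumour numbers, Xist and Eif2s3y as covariates, and a replicate block. Arrays with many zeros and probe set types were left out in further alternatives. Calculations outside limma used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

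Between tumours with title numbers 1 to 17 and those above 17, 2024 genes differed. Counts are therefore also given within a first range (tumours 1 to 17 and normal lungs 1 to 13) and a second range (tumours above 17 and normal lungs 14 to 20), and with the range as a block; the labels do not say that a range was processed together, and these ranges of normal lungs were chosen after the data were seen.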

Results

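The series holds 50 arrays, 31 from lung tumours of mice with the KrasLA allele and 19 from wild-type lungs. KrasLA is a latent allele that becomes an active Kras oncogene by spontaneous recombination in single cells, so that lung tumours arise without a virus or a carcinogen. The comparison asks which genes are expressed differently in these tumours and in normal lung. The median deposited intensity per array was 217.7 to 233.9. Of the arrays, 3 had more than 300 values listed at 0: normal lung 3 with 558, tumour 90 with 407 and normal lung 5 with 313. Their median correlations with their groups were 0.822, 0.920 and 0.882. Eif2s3y, a Y-linked gene, lay below 60 on 9 of 31 tumours and 5 of 19 normal lungs and above 90 on the others. Eif2s3y differed by 0.05 on the log2 scale between groups, and Kdm5d and Uty, also Y-linked, by 0.06 and -0.15; none of these passed the test. Xist, expressed from the inactive X chromosome of females, was listed at 0 on 12 of the 14 arrays with low Eif2s3y and read 849 and 929 on the others. On the 36 arrays with high Eif2s3y, Xist read 46.1 to 90.4. It is therefore given no fold.

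Compared with normal lung, 1691 of 8251 genes were higher in tumours and 2181 were lower. The balance moved with the scaling, to 2039 higher and 1816 lower with arrays centred on their median and to 1917 and 1948 with the values as deposited. The largest rise was that of Kng1, the precursor of the kinins, from 7.83 ± 0.17 to 10.65 ± 1.19 (log2 intensity, SD, n = 19 and 31), which is 7.05-fold (adjusted p = 8.11e-13, limma). Mt1, a metal-binding metallothionein, rose 4.95-fold and Adssl1, an enzyme of purine nucleotide metabolism, 4.88-fold. Ros1, a receptor tyrosine kinase, rose 4.63-fold, and each of these 4 genes was higher in all 31 tumours than in any normal lung. Chil3, a chitinase-like protein of macrophages, rose 4.10-fold, and Ctsh, a lysosomal protease that processes surfactant protein, 3.82-fold. With zeros at the floor the largest fall was that of Matn2, a matrix protein, from 10.32 ± 0.30 to 7.57 ± 0.57, or 6.72-fold lower (adjusted p = 6.34e-23). Inmt, Cdo1, Cavin2 and Car3, which have zeros in normal lungs, differed by more with zeros taken as missing (-3.35, -3.04, -2.90 and -2.79, against -2.75 for Matn2). Thbd, the endothelial thrombin receptor, was 6.60-fold lower, Myl7, an atrial myosin light chain, 6.25-fold lower, and Pon1, a lactonase, 5.71-fold lower. Spef1, a microtubule-binding protein of cilia and flagella, was 5.09-fold lower, the homeobox gene Vax1 5.05-fold lower and Hba-a1, alpha globin, 5.02-fold lower. At Matn2, Thbd and Spef1 a second, dimmer probe set differed by -0.03, -0.01 and -0.09 and did not pass. That of Thbd was listed at 0 on 11 normal lungs, and its difference has these zeros at the floor.

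Among the 24 largest changes, several genes had values listed at 0. Hpgd, which degrades prostaglandins, was listed at 0 on all 19 normal lungs and measured on all 31 tumours at 52.5 to 168; with zeros taken as missing it has no value in normal lung, so no direction can be given. Lcn2, an iron-carrier protein, was listed at 0 on 1 tumour and read 2401 to 7309 on the other 30, against 475 to 1247 in normal lungs. Apoc1, an apolipoprotein, and Vil1, an actin-bundling protein of the brush border, were also listed at 0 on 1 tumour each, with medians over measured tumours of 1884 and 106 against 341 and 32.6 in normal lungs. Inmt, a methyltransferase of lung fibroblasts, read 227 to 2274 in tumours and 5774 to 9475 on 17 normal lungs, with 2 listed at 0. Car3, a carbonic anhydrase, had a median of 48.8 in tumours and 387 on 17 normal lungs, with 2 listed at 0. Krtdap, a protein of differentiating keratinocytes, and Aldh1a1 were among the largest rises only with zeros at the floor, and with zeros taken as missing they differed by -0.12 and -2.46. Aldh1a1, a retinal dehydrogenase, was listed at 0 on 11 normal lungs, and the other 8 read 2890 to 4532, above all 31 tumours at 434 to 1316. Its 2 probe sets passed in opposite directions only with zeros at the floor. The second was then at -0.18, and the first was at -2.46 with zeros taken as missing. Krtdap was listed at 0 on 7 normal lungs, and its measured medians were 1236 in normal lungs and 1134 in tumours.

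Changes of at least 2-fold were found for 132 genes that rose and 146 that fell. With zeros taken as missing, 1954 genes were higher and 2600 lower, and 139 and 186 were so at least 2-fold. Within the first number range 1461 genes were higher and 1728 lower, within the second 1325 and 1771, and with the range as a block 1793 and 2234, of which 3777 were shared with the calls above. Of the genes named here, Fgf10, Gclc, Nqo1, Psmb8, Alas2 and Aldh1a1 did not pass in their direction within the first range, Inmt, Myh7, Klf6, Jun, Hspa1a and Nr1d1 did not within the second, and Krtdap and Xist did not within either. These fits keep zeros at the floor. Measured values of Inmt, Jun and Alas2 were lower in every tumour than in any normal lung, and those of Myh7 were higher. For these genes the loss within a range therefore does not show that the difference was absent there. Among all genes, 118 had probe sets that passed in opposite directions, and among listed genes these included C1qb, Bub1, Erbb3, Afp, Igf2, Fdps, Ighm, Plk1 and Rgs5.

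**Figure D1:**
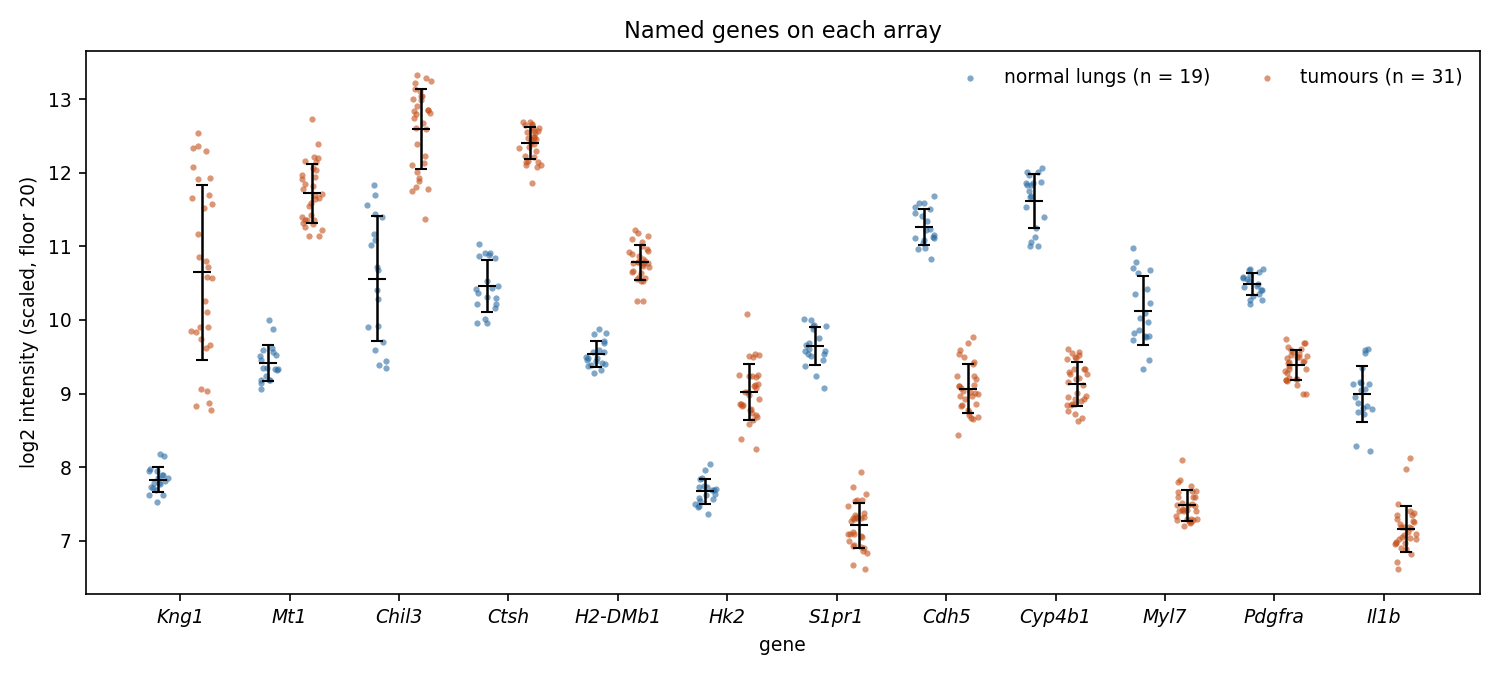
Log2 intensity of 12 named genes (x axis) on each of 19 normal lungs (blue) and 31 tumours (orange); bars show the mean ± SD. Kng1 spread widely among tumours (SD 1.19, against 0.17 in normal lungs), while S1pr1, Cdh5, Cyp4b1 and Myl7 were lower in every tumour than in any normal lung.

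Of the epithelial marker lists, that of alveolar type 2 cells, which make surfactant, rose, and those of the other lung epithelial cells fell. Of 14 measured type 2 markers, 8 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 1.41e-06). Sftpb, surfactant protein B, rose 2.42-fold, from 12.44 ± 0.23 to 13.72 ± 0.17, and Muc1, Cebpa and Napsa, chosen after their values were seen, rose by 1.19, 1.14 and 1.04 on the log2 scale. Sftpc, surfactant protein C, read 14.23 in tumours and 14.16 in normal lungs and did not pass. Of 8 alveolar type 1 markers, genes of the flat gas-exchange cells, 7 fell and 0 rose (7 and 0 over the list alone; adjusted p = 0.000802). Cyp2b10, a cytochrome P450, was 3.59-fold lower and Sema3e, a guidance factor, 1.51-fold lower, and Pdpn and Ager, chosen after their values were seen, fell by 0.42 and 0.39. Of 11 club cell markers, from the secretory cells of the airways, 8 fell and 2 rose (9 and 2 over the list alone; adjusted p = 0.000342). Cyp4b1 was 5.61-fold lower and Cckar 4.69-fold lower in tumours. The rises were Aldh1a1, which rests on zeros, and Selenbp1, by 0.30. With zeros taken as missing, 10 club cell markers fell and 1 rose. Cyp2f2 was listed at 0 on 1 normal lung and had medians of 617 in tumours and 4163 over the other 18. Of 7 ciliated cell markers 5 fell and 0 rose (5 and 0 over the list alone; adjusted p = 0.00108), with Tekt1, a tektin, 1.71-fold and Spa17 1.74-fold lower.

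Endothelial, stromal and muscle genes fell together. Dissected tumours were compared with normal lung, so the tissue that each sample held cannot be told apart from a change of expression within cells. Of 26 endothelial markers 20 fell and 0 rose (23 and 1 adjusted over the list alone; adjusted p = 3.39e-12), with a median of -1.15. S1pr1, a lipid receptor of endothelium, fell from 9.65 ± 0.26 to 7.21 ± 0.31 (5.40-fold lower, adjusted p = 7.36e-30) and Cdh5, VE-cadherin, from 11.26 ± 0.25 to 9.07 ± 0.33 (4.57-fold lower). The probe sets used for S1pr1, Thbd and Cyp4b1, and for Cldn7, Relb, Myh7 and Vpreb3 among the other genes named, are of the type marked f, whose probes are shared with similar sequences, and a second probe set of S1pr1 differed by 0.08 and did not pass. Of the endothelial markers, 23 fell and 0 rose with zeros taken as missing. Of 25 fibroblast and matrix markers 19 fell and 1 rose (19 and 1 over the list alone; adjusted p = 1.59e-07). Tcf21, a transcription factor of lung mesenchyme, was 2.03-fold lower and Pdgfra, a growth factor receptor of fibroblasts, 2.13-fold lower, while its other probe sets differed by -0.09 and -0.15 and did not pass. Fgf10, a mesenchymal growth factor, rose by 0.21, while Fn1 and Col1a2 differed by 0.00 and 0.04 and did not pass. Of 12 smooth muscle and pericyte markers 7 fell and 0 rose (7 and 0 over the list alone; adjusted p = 0.000802), including Myl9 (2.45-fold lower) and Myh11, smooth muscle myosin (2.18-fold lower). Of 20 heart and skeletal muscle markers 11 fell and 2 rose (12 and 2 over the list alone; adjusted p = 0.000341). Those that fell included atrial and ventricular genes: Myl7, and Myl4, which was 3.48-fold lower, and Tnnt2 and Myh6, chosen after their values were seen, which fell by 2.02 and 1.73. Myh7, slow myosin heavy chain, rose in the test. It was listed at 0 on 1 tumour and read 810 to 3360 on the other 30, against 572 to 756 in normal lungs. Of 5 erythroid markers 4 fell and 0 rose (4 and 0 over the list alone), with Hba-a1 and Alas2 among those that fell, and the list did not pass (adjusted p = 0.0549). It passed with zeros taken as missing (0.0191). Alas2 was listed at 0 on 1 normal lung and had medians of 356 in tumours and 1236 over the other 18.

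**Figure D2:**
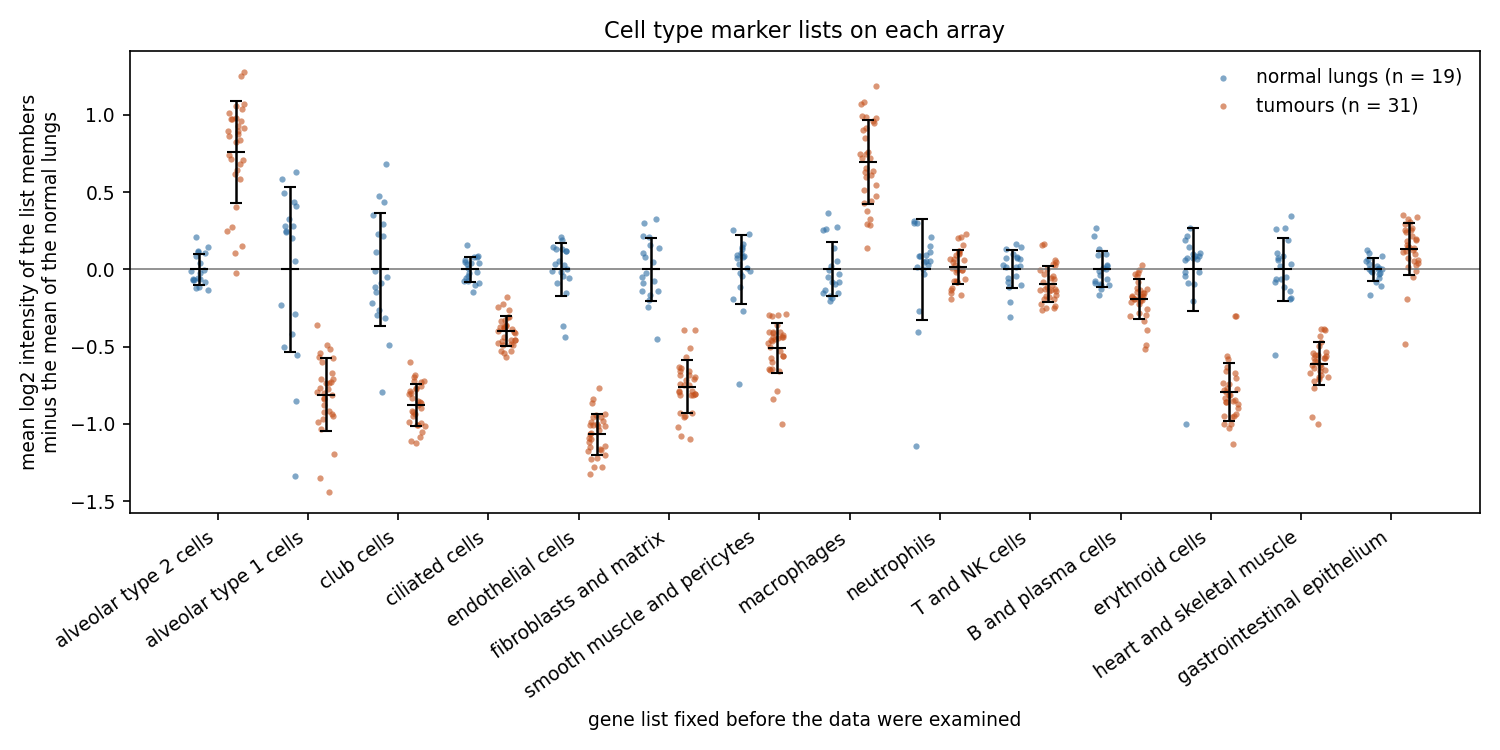
Mean log2 intensity of the measured members of 14 cell type lists (x axis) on each array, relative to the mean of the normal lungs (y axis); blue points are 19 normal lungs, orange points 31 tumours, bars the mean ± SD, with zeros at the floor. The tumours lay 1.07 below normal lungs for endothelial cells and 0.76 above for alveolar type 2 cells.

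Macrophage and antigen presentation genes rose, and lymphocyte genes were slightly lower. The MHC class II presentation list was set as a pathway, not a cell type, and which cells carried its rise was not tested. Of 19 macrophage markers 13 rose and 0 fell (13 and 0 over the list alone; adjusted p = 2.31e-06), with a median of 0.71. Cd14, a lipopolysaccharide co-receptor, rose 1.93-fold, from 9.45 ± 0.14 to 10.40 ± 0.32. C1qb, of complement C1q, rose 2.69-fold at the probe set used, while its second, dimmer probe set fell by 0.25. Of 10 MHC class II presentation genes 8 rose and 0 fell (8 and 0 over the list alone; adjusted p = 7.48e-08). H2-DMb1, which loads peptides, rose 2.37-fold and Cd74, the invariant chain, 1.94-fold, each above all normal lungs in 31 of 31 tumours. Their regulator Ciita differed by 0.07 and did not pass. With the correlation of the MHC class II list estimated from the data, at 0.285, its adjusted p was 0.00877 (camera). Of 21 T and NK cell markers 12 fell and 0 rose (12 and 0 over the list alone), with a median of -0.17; Gzmb, a cytotoxic protease, was 1.18-fold and Cd7 1.28-fold lower. The list passed at an adjusted p = 0.0483 and did not pass with an estimated correlation (adjusted p = 0.351) or without normal lung 3 (0.0583). Of 16 B and plasma cell markers 9 fell and 1 rose (9 and 1 over the list alone; adjusted p = 0.0353, and adjusted p = 0.156 with an estimated correlation). Prdm1, a plasma cell regulator, was 1.43-fold lower, Vpreb3 was listed at 0 on 1 normal lung, with medians of 59.4 in tumours and 155 over the other 18, and Pou2af1, a B cell coactivator, was 1.36-fold higher. Of 14 neutrophil markers 2 rose and 4 fell (2 and 4 over the list alone; adjusted p = 0.989): Mmp9 and Csf3r were 1.15-fold and 1.12-fold lower, and Hdc, which makes histamine, was 2.02-fold higher. Among neutrophil markers, 2 rose and 7 fell with zeros taken as missing, the median turned from 0.01 to -0.12, and the list still did not pass (adjusted p = 0.319). S100a9 and S100a8, chosen after their values were seen, were then lower in tumours, with medians of 89.7 and 317 against 191 and 484 over the normal lungs that measured them.

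Transcripts that the MAPK pathway is known to induce rose, whereas the components of the Ras pathway moved both ways. Of 13 measured feedback and output genes 7 rose and 0 fell (7 and 0 over the list alone; adjusted p = 0.00155). The list score was above all normal lungs in 31 of 31 tumours. Ccnd1, cyclin D1, rose 1.80-fold, from 9.52 ± 0.25 to 10.37 ± 0.26, and Epha2, an ephrin receptor, 1.35-fold; Phlda1 and the ERK phosphatase Dusp6, chosen after their values were seen, rose by 1.35 and 1.14. Etv4, Spred2, Fosl1 and Ier3 differed by -0.05 to 0.08 and did not pass. Of 22 Ras pathway components 8 rose and 9 fell (8 and 9 over the list alone; adjusted p = 0.685). Map2k1, the kinase MEK1, was 1.37-fold higher, and Rras and Egfr were 1.23-fold and 1.17-fold lower. The median of this list was -0.05 and its mean 0.06.

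Glycolytic genes rose, whereas the lipid synthesis list did not pass and its members moved both ways. Of 12 measured glycolysis genes 9 rose and 0 fell (9 and 1 over the list alone; adjusted p = 5.31e-05). Hk2, a hexokinase, rose 2.55-fold, from 7.67 ± 0.17 to 9.02 ± 0.38, and Ldha, lactate dehydrogenase A, 2.01-fold; a second, dimmer probe set of Hk2 did not pass. Of 18 fatty acid and sterol synthesis genes 7 rose and 4 fell (7 and 4 over the list alone), and the list did not pass (adjusted p = 0.0829). It passed with zeros taken as missing (0.0237). Fasn, fatty acid synthase, rose 2.17-fold and Acly, which supplies its acetyl-CoA, 1.83-fold, whereas Gpam, of triglyceride synthesis, was 2.12-fold lower. Of the sterol branch, which had no list of its own, Hmgcs1, Sqle and Lss differed by 0.13, 0.01 and -0.02 and did not pass. Fdps, of the same branch, had probe sets that passed in opposite directions, at 0.25 and -0.125. Of 16 endoplasmic reticulum stress genes 8 rose and 1 fell (9 and 1 over the list alone; adjusted p = 0.0101, and adjusted p = 0.103 with an estimated correlation). Xbp1, a transcription factor of secretory cells, was 1.53-fold higher, Hsp90b1, a chaperone, 1.31-fold higher and Hyou1, another chaperone, 1.18-fold lower. Of 17 NRF2 and glutathione genes 3 rose and 1 fell (3 and 1 over the list alone; adjusted p = 0.986). Txnrd1 and Gclc were 1.27-fold and 1.07-fold higher, and Nqo1, listed at 0 on 1 tumour, had medians of 71.9 in tumours and 84.9 in normal lungs. Members that rose and fell numbered 5 and 4 with zeros taken as missing.

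Cell cycle genes did not rise as a group. Of 29 measured members 3 rose and 6 fell (3 and 6 over the list alone; adjusted p = 0.989), and the median was 0.04 and the mean -0.05. Top2a, a topoisomerase of dividing cells, was 2.50-fold lower and Bub1, a spindle checkpoint kinase, 1.53-fold lower at the probe set used, while another probe set of Bub1 rose by 0.50. Birc5, survivin, was 1.38-fold higher. Mki67 and Pcna, common markers of proliferation, differed by 0.18 and 0.06 and did not pass. With zeros taken as missing, 8 members rose and 6 fell, and the list still did not pass (camera adjusted p = 0.537). Cdc20 and Cdk1, chosen after their values were seen, were listed at 0 on 3 and 2 tumours. Their measured medians were 178 and 227 in tumours and 126 and 179 in normal lungs. Of 14 p53 targets and senescence genes 5 rose and 3 fell (6 and 3 over the list alone; adjusted p = 0.143). Bhlhe40, a transcriptional repressor, was 2.63-fold and Gadd45a, a stress protein, 1.76-fold higher, Cdkn1a (p21), chosen after its value was seen, rose by 0.97, and Fas, a death receptor, was 2.01-fold lower. Cdkn2a, the Ink4a/Arf locus, differed by 0.05 and did not pass. Of 13 fetal lung and oncofetal genes 5 rose and 6 fell (5 and 6 over the list alone; adjusted p = 0.989); Sox11 was 3.04-fold and Igf2bp1 1.25-fold lower, and Foxm1, a regulator of mitotic genes, was 1.41-fold higher, while its other probe set differed by -0.02 and did not pass.

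Of 19 epithelial junction and simple keratin genes 7 rose and 4 fell (7 and 4 over the list alone; adjusted p = 0.152; 0.0150 with zeros taken as missing). Spint1, a protease inhibitor, was 2.58-fold and Cldn7, a claudin, 1.73-fold higher, and Tjp1 (ZO-1) was 1.88-fold lower at the brighter of its probe sets. Of 22 gastrointestinal epithelium markers 4 rose and 3 fell (4 and 3 over the list alone; adjusted p = 0.554). Ctse, cathepsin E, was 2.75-fold higher at the brightest of its probe sets, with -0.20 and 0.04 at the others. Another probe set of Ctse was listed at 0 on 6 tumours, and its difference has these zeros at the floor. Ttr, transthyretin, was 1.25-fold lower. Tff1, Tff2, Tff3 and Cdx2 differed by -0.07 to 0.13 and did not pass. Taking zeros as missing, 8 gastrointestinal markers rose and 4 fell (adjusted p = 0.319). Of 18 interferon response genes 2 rose and 8 fell (2 and 8 over the list alone; adjusted p = 0.0870; 0.00571 with zeros taken as missing). Ifitm3 was 1.88-fold and Irf1 1.34-fold lower, and Psmb8, an immunoproteasome subunit, was 1.25-fold higher. Of 18 NF-kB cytokine genes 4 rose and 3 fell (4 and 3 over the list alone; adjusted p = 0.986); Relb was 2.40-fold higher, with 0.06 at its other probe set, Cxcl1 was 1.28-fold higher, and Il1b was 3.56-fold lower. The next lists bear on how samples were handled. Of 16 immediate early genes 1 rose and 4 fell (1 and 3 over the list alone; adjusted p = 0.986), with Hspa1a 1.34-fold higher, Klf6 1.17-fold lower, and Jun listed at 0 on 1 normal lung, with medians of 238 in tumours and 484 over the other 18. Of the immediate early genes, 3 rose and 8 fell with zeros taken as missing (adjusted p = 0.297). Of 11 circadian genes 0 rose and 3 fell (0 and 3 over the list alone; adjusted p = 0.260), with Nr1d1 1.35-fold and Clock 1.33-fold lower. For the cell cycle, NF-kB, immediate early and NRF2 lists the direction of the test was up, whereas the mean was below 0; with zeros taken as missing it was down for the NF-kB and immediate early lists.

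**Figure D3:**
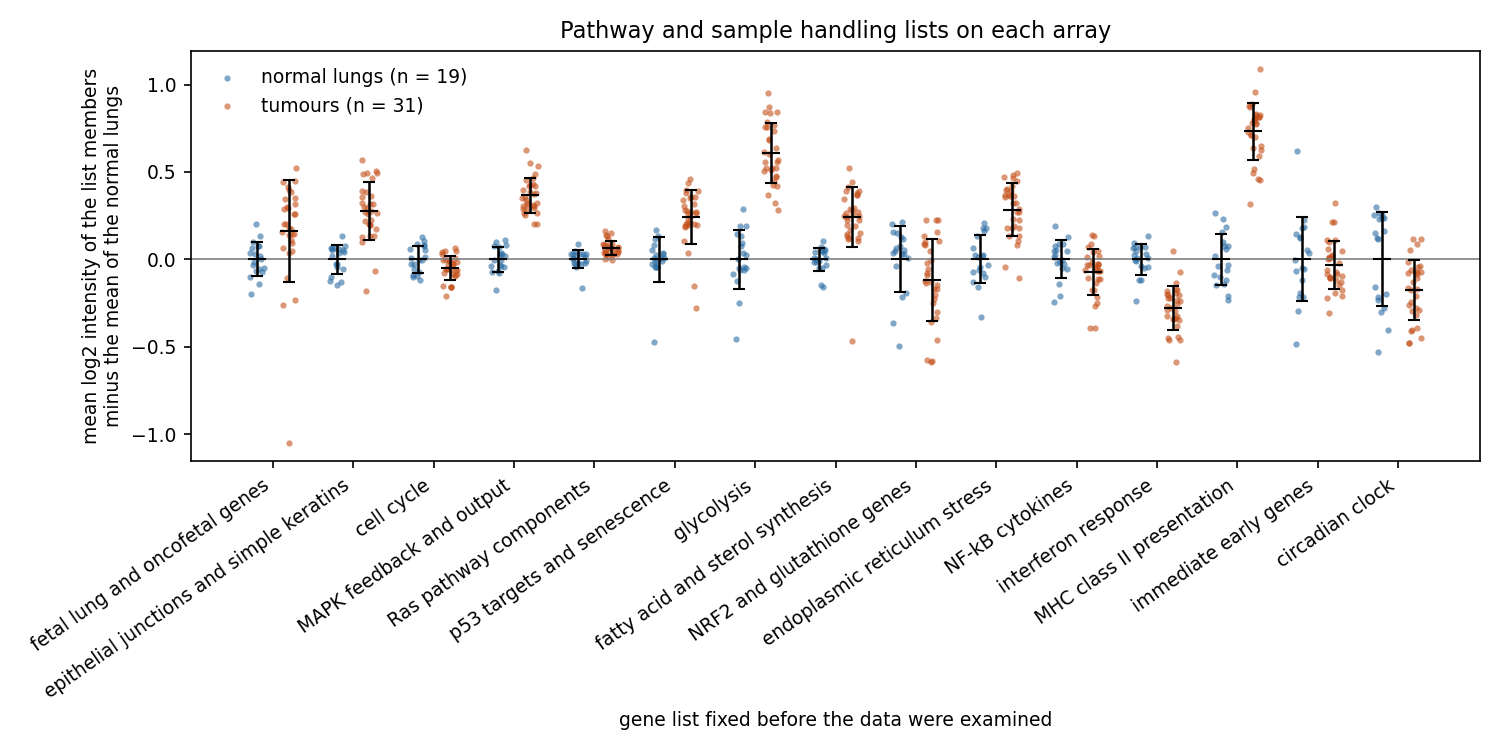
Mean log2 intensity of the measured members of the pathway and sample handling lists (x axis) on each array, relative to the mean of the normal lungs (y axis); blue points are 19 normal lungs, orange points 31 tumours, bars the mean ± SD, with zeros at the floor. MHC class II presentation (0.73 above normal lungs) and MAPK feedback (0.37 above) separated all 31 tumours from all normal lungs, and the cell cycle list did not (0.05 below).

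In all, 15 of 29 tested lists passed, and 12 did so with an estimated correlation. The adjusted p of these 12 then ran from 2.07e-06 for endothelial cells to 0.0254 for heart and skeletal muscle (camera). It was 0.00877 for MHC class II presentation, 0.0137 for macrophages and 0.00632 for fibroblasts and matrix, so the p-values at the preset correlation are far smaller. In 99 random regroupings of the arrays, the median was 1 list called and the highest 12. Within the first number range all 15 kept their call and direction. Within the second range 13 did, without the T and NK and the B and plasma cell lists, and with the range as a block 14 did, without the T and NK cell list.

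Whether tumours with more of one list had more or less of another was tested for 8 pairs of lists across the 31 tumours, and 0 pairs passed after adjustment. At an unadjusted permutation p under 0.05, 0 pairs passed by Pearson's r and 2 by Spearman's rho. The strongest was that of T and NK cells with MHC class II presentation (Pearson's r = -0.35, permutation p = 0.0546, adjusted p = 0.411; Spearman's rho = -0.41, adjusted p = 0.166). Its r was -0.27 without the 2 tumours farthest from the median, -0.33 and -0.28 within tumours numbered 1 to 17 and above 17, and -0.22 with quantile normalization. With arrays centred on their median it passed by rank (r = -0.40, adjusted p = 0.197, and rho = -0.51, adjusted p = 0.0278). Within the 19 normal lungs this pair had r = -0.51 (permutation p = 0.0238, adjusted p = 0.0952), so the negative sign was not particular to tumours. By Pearson's r the lowest adjusted p there was 0.0593, for cell cycle with type 2 cells (r = -0.60, against -0.06 across tumours). Cell cycle and macrophage scores had r = -0.26 (adjusted p = 0.411) and rho = -0.30 (adjusted p = 0.210). Within tumours numbered 1 to 17 this was r = -0.76 (adjusted p = 0.00928), and above 17 it was r = 0.22 (adjusted p = 0.683), so the relation did not hold in both ranges; the difference between ranges was not tested. With zeros taken as missing 3 pairs passed: cell cycle with macrophages (r = -0.54, adjusted p = 0.0118), alveolar type 2 cells with gastrointestinal epithelium (r = -0.46, adjusted p = 0.0398) and alveolar type 2 with type 1 cells (r = 0.42, adjusted p = 0.0485).

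Tumours were not shown to vary more than normal lungs over all genes. The SD was larger among tumours for 57.8% of genes (permutation p = 0.447), and 697 genes were more variable among tumours and 431 among normal lungs. Among tumours numbered 1 to 17 alone the share was 45.1%, with 495 genes more variable among tumours and 628 among normal lungs, and with those above 17 it was 50%, with 413 and 389. With zeros taken as missing these were 452 and 50 (59.6%, permutation p = 0.364). Without zeros as well as normal lungs 3 and 5 and tumour 90, the share was 68.5% (permutation p = 0.0477).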

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

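The alternatives with zeros taken as missing, with arrays left out by their zeros, with Eif2s3y as a covariate, without probe sets of shared types and with title-number ranges of tumours and normal lungs were chosen after the data were seen; the others were set before. Of 140 recomputed counts and shares 131 stayed within 1.5 times the reported value or on the same side of the test. The number of genes called was 2152 without the dimmer genes (4126 of 8251 genes kept), with 1106 higher, 1046 lower and 178 changed at least 2-fold, since fewer genes were tested. The number of genes changed at least 2-fold, 278, was 684 at 1.5-fold and 71 at 3-fold, by construction. Of 8 relations between lists, 1 passed by Pearson's r within tumours numbered 1 to 17 (cell cycle with macrophages) and 3 with zeros taken as missing. By Spearman's rho, type 2 with type 1 cells also passed within tumours 1 to 17 (rho = 0.74, adjusted p = 0.0199), and T and NK cells with MHC class II presentation passed with arrays centred on their median; the cause was not tested. The share of genes with a larger SD among tumours was 68.5% with zeros taken as missing and without normal lungs 3 and 5 and tumour 90, the setting in which it passed; over the other settings it ran from 45.1% to 62.6%. Of 2261 recomputed values of 93 named genes, 2216 kept direction and call, 42 no longer passed and 3 reversed. Krtdap was -0.12 and Aldh1a1 -2.46 with zeros taken as missing, because the zeros of normal lungs no longer counted as low. Aldh1a1 was -0.13 within the first number range, where zeros stayed at the floor. Its 8 measured normal lungs lay above all 31 tumours, so its sign in such a fit depends on how many normal lungs were listed at 0. Tekt1, Fas and Hyou1 did not pass at a floor of 100, which lies above their mean values, and Bub1 did not with the mean of its probe sets. Of 722 recomputed list tests, 671 were on the same side of the threshold, 24 no longer passed and 27 newly passed, and 0 called lists turned direction while called. The T and NK cell and B and plasma cell lists were the ones lost most often; heart and skeletal muscle was lost without the dimmer genes, and endoplasmic reticulum stress there and with the estimated correlation. Title numbers shared by 14 tumours and normal lungs do not pair them. With this number as a replicate block, 1558 genes were higher and 1840 lower (3398 in all) on 28 arrays; the same-number correlations of these pairs ran from -0.13 to 0.14, and 1 tumour correlated best with the normal lung of its number. Kras could not be recomputed because no probe set carries its name, gene lists were not run with every probe set on its own or with the rank test, and Xist as a covariate carries little because Xist was listed at 0 on 12 arrays. Signal near the floor limits small differences: 2.96% of values lay under 20.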

Other observations

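The predictions for zeros as low signal and for the number range behind the marker changes were written before their results, although the range was chosen after the data were seen; the comparison of SDs was planned, and the other tests below were chosen after the results were seen. Some genes with values listed at 0 differed widely in the measured values; those described next were chosen after their values were seen. Clu, clusterin, a secreted chaperone, was listed at 0 on 5 tumours and read 1820 to 9958 on the other 26, against 640 to 1258 in normal lungs. The imprinted neighbours Meg3, a noncoding RNA, and Dlk1, a Notch ligand relative, were listed at 0 on 3 and 4 tumours and had measured medians of 2233 and 808 in tumours against 489 and 298 in normal lungs. Dlk1 reached 7677 in 1 tumour. On the side of normal lung, Hopx, a marker of alveolar type 1 cells, was listed at 0 on 6 normal lungs and read 4289 to 6446 on the other 13, against 744 to 2918 in tumours. Cdo1, a cysteine dioxygenase, Cavin2, of caveolae, and Gsn, the actin-severing gelsolin, were listed at 0 on 8, 10 and 6 normal lungs, with medians of 733, 1449 and 5495 on the others against 91.7, 204 and 953 in tumours. The tight junction gene Cldn5, of endothelium, was listed at 0 on 3 normal lungs and had medians of 1696 over the other 16 and 290 in tumours.

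Some genes varied widely from tumour to tumour. With zeros at the floor, and again without zeros and without normal lungs 3 and 5 and tumour 90, 361 genes without zeros were more variable among tumours in both settings and 33 among normal lungs. These counts pool both ranges of tumour numbers; within tumours 1 to 17 alone 495 genes were more variable among tumours and 628 among normal lungs, and above 17 the counts were 413 and 389. Those named next were chosen after their values were seen. Kng1 spanned 8.78 to 12.54 (log2) among tumours and 7.54 to 8.18 among normal lungs. Csrp2, a LIM domain protein, had SDs of 0.83 and 0.12, Ctsk, cathepsin K, 0.76 and 0.15, and Itih4, a secreted protease inhibitor heavy chain, 0.70 and 0.14. Rbp4, the retinol carrier, had SDs of 0.82 and 0.24, Hdc 0.78 and 0.24, and Bgn, a matrix proteoglycan, 0.71 and 0.21.

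Of the values listed at 0, a low signal predicts that a second probe set of the same gene is low on that array too. It was in its lowest 25% at 9.30% of 355 pairs of a zero and a second probe set (95% exact binomial interval 6.49 to 12.8, pairs taken as independent), which argues against low signal. It was in its highest 25% at 68.5% (63.3 to 73.3), which argues against zeros placed without regard to level, and at genes at least 2-fold apart 97.0% of zeros fell in the group with the higher measured values, against 43.6% from the group sizes. That zeros replace mostly high values stays open as a hypothesis from these same data. The authors' processing step and a biological explanation were not tested.

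Tumours numbered 1 to 17 in their titles differed from those numbered above 17 at 2024 genes (1199 higher, 825 lower), mostly by little: the median size was 0.24 on the log2 scale, and 8 genes differed at least 2-fold. A random division of independent tumours is argued against, since 1 of 100 splits of the 31 tumours, the real one, gave as many. The highest other gave 65. These splits do not keep tumours of 1 mouse together, because the labels do not tie tumours to mice. Arrays of poor quality are argued against by 2504 genes without tumours 49 and 90. A processing batch that normal lungs passed through too may contribute: the difference between normal lungs 1 to 13 and 14 to 20 correlated with that in tumours over genes at 0.292, against at most 0.215 in 99 other splits, and 250 of 253 genes called in both had the same sign (94.9 shared genes from independent lists). The boundary of 13 was chosen from these data, and with it searched in each of 100 orders the highest other was 0.240. Of the genes called in tumours, 84.7% had the same sign in normal lungs; how much of the difference a batch accounts for, and mice and dates behind the numbers, were not tested, and no gene list passed (lowest adjusted p = 0.489).

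Markers of endothelial, stromal, airway and type 1 cells fell, and those of type 2 cells and macrophages rose. A lower share in tumours of every cell type other than type 2-like cells would lower macrophage and endothelial markers alike, but the macrophage list rose over the endothelial list by 1.76 on the log2 scale (SE 0.0736), which argues against it as the whole explanation. This difference restates list values given above and was chosen after they were seen, so it is not independent evidence. All 90 called members of 8 lists kept direction and call, 100% with Eif2s3y as a covariate and 100% with the range as a block. Eif2s3y was low on 9 of 31 tumours and 5 of 19 normal lungs, and the first range held 15 tumours and 12 normal lungs. Since both were spread over the 2 groups, neither covariate could remove much of a tumour difference. The refits were therefore nearly sure to keep the calls and decide little. Only the spread of low Eif2s3y and of the number range, as set here, over both groups argues against them as the whole explanation. A batch that separates tumours from normal lungs was not tested. Individual tumours were dissected and set against normal lung. Lower airway, vessel and muscle markers therefore cannot be told apart from a difference in the tissue sampled. More macrophages, or macrophages in another state, and tumour cells that may keep type 2 expression stay open and were not tested.

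Random splits of single arrays did not reach the real counts of genes or the real number of lists. They do not keep arrays of 1 mouse or number range together, so such grouping is not excluded by them. Of 100 splits into 31 and 19, 1 gave as many genes as the real 3872 (highest other 59), 1 gave as many at 2-fold as 278 (highest other 1), and 1 gave as many lists as 15 (highest other 12); each was the real split. The list test calls lists readily, however: 60 of the 99 other splits called at least 1 list, 56 of them with 0 genes called, so a list call close to the threshold is weak evidence. For the larger SD among tumours chance is not excluded: 4471 of 10001 permutations, the real one included, gave a share as far from 50% as 57.8%, and the highest was 83.8%.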
